A study of Zea mays with 8 samples.

How the data were processed

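Endosperm RNA of maize (Zea mays, W22 background) was profiled by RNA sequencing 12 days after pollination in 8 libraries. They are 4 libraries of normal kernels and 4 of kernels labelled ded1-ref, and the design text states that each mutant pool was paired with a pool of its normal siblings. Per the labels, the libraries were made from total RNA with a kit that does not mark strand, with a median insert of 200 bp, and 2 ends of 100 bp were read. Without strand, reads of a gene and of an overlapping or antisense partner cannot be told apart. Per the submitters' processing notes, cutadapt 1.1, Trimmomatic 0.22 and GSNAP 2013-07-20 were used. The read counter, the genome build and whether reads or read pairs were counted are not given in the sources used here. The gene IDs are those of the v3 annotation named in the labels.

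The authors deposited length-scaled transcript shares (TPM) for 63293 transcript rows in each library, and every library has the same sum, so that TPM keeps no depth. They also deposited a table of their own comparison, and per the file headers it has the columns of DESeq2: a mean normalized signal over the libraries, a log2 fold change of ded1-ref over normal with its standard error on the log2 scale, a test score, a p-value and an adjusted p-value. A mean of 0 and no fold is given for 24566 rows of the authors' table. The deposited score has the opposite sign of the deposited fold in 38727 of the 38727 rows with a fold. The direction was therefore taken from the header of the fold column and from the TPM. The largest deposited standard error of a log2 fold is 0.628.

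No column holds counts, but the authors' mean signal and the TPM together fix the reads behind each value. Solving for them gave whole numbers, to within 0.05 reads, for 100% of 236228 values above 0. Size factors computed from the recovered reads as medians of ratios differed from those implied by the authors' table by a relative 5.5e-09 at most. The recovered totals ran from 10536845 to 20725033 reads per library. Over rows that held 1 read, the median value was 0.0363 TPM in the deepest library and 0.0823 TPM in the shallowest.

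Rows were summed to 39423 genes. Genes with at least 1 TPM in at least 4 libraries were tested, 13671 in all. The plan assumed counts and named limma-trend on log2(TPM + 1) for the case that the tables hold none, so this was the main test. It was fitted with limma 3.58.1 in R 4.3.3 with the replicate number as a block, and adjusted by the Benjamini-Hochberg method at 0.05. All adjusted p-values of genes are from limma. A fold on the log2(TPM + 1) scale understates the change of low genes. The block follows the stated pairing. Deviations from the group means of libraries with the same number correlated at 0.115, 0.333, 0.309 and 0.149 in the 4 pairs.

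TPM are shares, and on this scale the median tested gene was lower by 0.68 log2 units in the libraries labelled ded1-ref (a median change of -0.68). The same test was therefore also read on TPM divided by median-of-ratios factors, an alternative chosen beforehand that brings the median change to -0.0031; this is called the scaled test. Changes relative to the median gene are given from it. A gene is said to have risen or fallen only where the TPM test and the scaled test passed in that direction, and values are given otherwise. Because the median gene is lower on the TPM scale, this rule asks more of a rise than of a fall. Other alternatives were upper quartile scaling, limma-voom on the recovered reads with size factors or library totals, another pseudocount (0.1), no filter, a minimum of 10 reads, no block, each replicate left out, transcript rows, and TPM set again without zein genes. The count models of the plan were not run.

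The test was tried on simulated data built for ded1-ref against normal, and over 13245 tested genes it called 4 of 65 genes changed 1.5-fold, 30 of 61 changed 2-fold and 66 of 66 changed 4-fold. Of its calls, 5.66% were false. The simulation changed few genes, gave all genes the same dispersion and built in no pair effect and no shift of the median gene. Its false share therefore does not measure that of the TPM test on the real libraries.

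Names came from a table of Zm-B73-REFERENCE-NAM-5.0 genes, used for names alone, and no positions are given because the build of the files is not stated. It matched 18771 of the 39423 genes by ID or synonym and gave an informative name to 2632. Before the data were examined, 9 gene lists were fixed by symbol: basal transfer layer, embryo-surrounding region, endosperm adjacent to scutellum, aleurone, embryo, maternal kernel tissue, imprinted endosperm, starch synthesis and grain-fill transcription factor genes. A gene recorded as a correction to these symbol matches was left out of its list. The other lists of the plan rested on gene descriptions, which the name table does not hold. In their place 16 lists were written by name pattern after the names were seen and before any test between the groups: zein, transfer layer antifungal and response, glycolysis and fermentation, late embryo-type storage and desiccation, histone, DNA replication and cell cycle, auxin, cytokinin, MYB, NAC with WRKY and bZIP, heat shock, ER protein folding, ribosomal protein, amino acid metabolism, protease inhibitor and defence, and cell wall genes. Lists were tested with camera in limma with a preset correlation of 0.01 between genes, adjusted over 23 lists, and again with an estimated correlation. Shares of a library were compared by an exact two-sided permutation test over the 70 assignments of 4 against 4 libraries, whose smallest p is 0.0286.

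The named genes follow a rule fixed before the data were examined. They are ded1, the 10 genes with the largest positive and the 10 with the largest negative log2 change among named genes past the threshold that changed the same way in 4 of 4 pairs and reached a mean of 5 TPM in the higher group, and up to 4 members of each list with the smallest adjusted p (or, with none called, the 2 with the highest level). Any other gene was named after its values were seen. Near-identical zein genes share reads, and how reads with several hits were counted is not given in the sources used here, so values of single zein genes are uncertain and family sums less so. Tables and tests used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.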

Results

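RNA from endosperm, the storage tissue of the maize kernel, was measured by RNA sequencing 12 days after pollination in 8 libraries. The mutation ded1-ref affects ded1 (GRMZM2G121570), which is known to encode a MYB family transcription factor of the endosperm. Pools of kernels labelled ded1-ref were paired with pools of their normal siblings, with 4 pools in each group, and the labels describe the pools as biological replicates. The normal libraries held 14618530, 10536845, 16246294 and 13004853 recovered reads in replicates 1 to 4, and the libraries labelled ded1-ref held 20725033, 17810464, 13924952 and 16137250. The comparison asks which endosperm genes differ between mutant and normal sibling kernels. Levels below are means ± SD over the 4 libraries of a group (n = 4), and log2 changes are ded1-ref minus normal.

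The targeted gene was higher, not lower, in the libraries labelled ded1-ref. ded1 stood at 42.0, 40.2, 38.5 and 37.0 TPM in normal replicates 1 to 4 and at 67.3, 69.7, 101 and 67.4 TPM in ded1-ref replicates 1 to 4. The means were 39.4 ± 2.18 TPM in normal endosperm and 76.3 ± 16.3 TPM in the libraries labelled ded1-ref (SD, n = 4). The log2 change was 0.91 ± 0.15 (SE) on the TPM scale (limma adjusted p = 2.9e-04) and 1.74 ± 0.19 in the scaled test (limma adjusted p = 3.0e-04), with a higher level in 4 of 4 pairs. The authors' deposited table gives a log2 fold of 1.77 for ded1. The labels do not say whether the lesion alters the transcript, so its level does not check which libraries are mutant. Every direction below therefore refers to libraries as labelled.

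In the libraries labelled ded1-ref 482 genes rose and 1444 genes fell on both scales, among 13671 tested. The 482 are all genes higher on the TPM scale and the 1444 all genes lower in the scaled test. The rule is thus stricter for rises, and the excess of falls does not show that more genes fell than rose relative to the median gene. Among genes with an informative name, those that fell were led by yuc, an auxin synthesis gene, and by fl3, an endosperm transcription factor gene of the floury kernel mutants. Those that rose were led by flavonoid genes and by members of the alpha zein family, the main storage proteins of the kernel. On the TPM scale alone 482 genes were higher and 9539 lower, so that 4.81% of the calls were higher. In the scaled test, in which the median gene does not move, 1687 were higher and 1444 lower, so that 53.9% were higher. The scaled count of lower genes was 917 without replicate 2. At a change of at least 2-fold, 626 genes were higher and 518 lower in the scaled test, against 177 and 3004 on the TPM scale. The first principal component of log2 TPM held 71.7% of the variance and separated the groups, from -64.4 to -40.8 in the normal libraries and from 26.1 to 74.2 in those labelled ded1-ref.

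**Figure D1:**
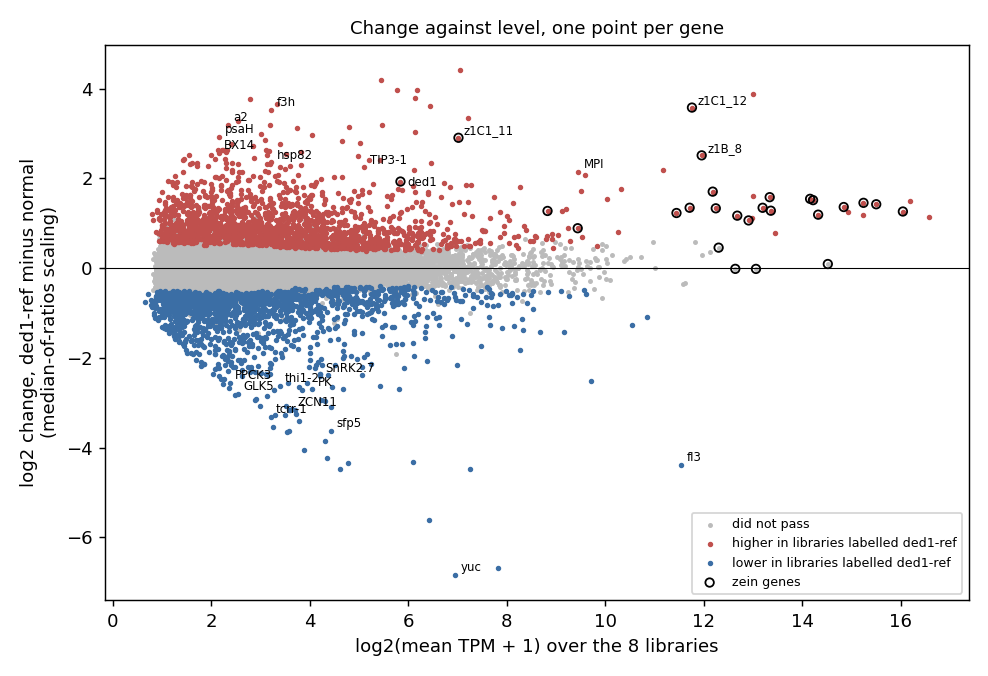
Log2 change between the libraries labelled ded1-ref and normal in the scaled test (vertical axis) against the log2 of the mean TPM plus 1 (horizontal axis), 1 point per tested gene. Red points are the 1687 genes that were higher, blue points the 1444 that were lower and grey points those that did not pass. Black circles mark the 26 zein genes, 22 of which were higher in this test, and names mark ded1 and the genes with the largest changes that pass the naming rule; yuc lies lowest among the named genes, at -6.84.

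Among named genes, yuc (GRMZM2G091819) fell most. It went from 245 ± 57.1 TPM in normal endosperm to 0.484 ± 0.292 TPM (SD, n = 4), a log2 change of -7.37 ± 0.22 (SE) on the TPM scale and -6.84 in the scaled test (limma adjusted p = 2.3e-10 and 7.1e-07). fl3 (GRMZM2G006585) was among the abundant transcripts of normal endosperm, at 5794 ± 1178 TPM, and fell to 178 ± 115 TPM (log2 change -5.23 ± 0.20 SE, limma adjusted p = 2.9e-09). sfp5 (GRMZM2G444801) fell from 39.9 ± 7.40 to 1.15 ± 0.460 TPM. tcrr-1 (GRMZM2G016145), a response regulator of transfer cells, fell from 16.2 ± 6.85 to 0.202 ± 0.167 TPM. ZCN11 (GRMZM2G117057), of the family that includes flowering signals, fell from 22.3 ± 6.03 to 0.714 ± 0.215 TPM. It was the 1 matched and tested gene of the list for endosperm adjacent to scutellum, where adjustment over the list alone leaves the same call. The remaining genes of this group were PK, thi1-2 (thiamine synthesis), GLK5, SnRK2.7 (a protein kinase) and PPCK3 (a kinase of phosphoenolpyruvate carboxylase). Their log2 TPM changes ran from -3.37 for PK to -2.94 for PPCK3. Each of the 10 genes was lower in 4 of 4 pairs on both scales, which the naming rule requires on the TPM scale.

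Among the 10 named genes that rose most, f3h and a2 are flavonoid pathway genes, z1C1_12, z1C1_11 and z1B_8 are alpha zein genes, and the others were psaH, BX14, hsp82, TIP3-1 and MPI. f3h (GRMZM2G062396), flavanone 3-hydroxylase, went from 0.765 ± 0.357 to 15.8 ± 11.8 TPM (SD, n = 4; log2 change 2.99 ± 0.32 SE, limma adjusted p = 1.2e-05). a2 (GRMZM2G345717), of the anthocyanin pathway, went from 0.0783 ± 0.0786 to 8.08 ± 5.69 TPM (log2 change 2.81 ± 0.32 SE, limma adjusted p = 2.0e-05). psaH (GRMZM2G451224), a subunit of photosystem I, rose from 0.309 ± 0.356 to 6.63 ± 2.95 TPM, and BX14 (GRMZM2G127418), of benzoxazinoid synthesis, rose from 0.755 ± 0.211 to 6.13 ± 0.643 TPM. hsp82 (GRMZM5G833699), a chaperone gene, rose from 3.43 ± 1.08 to 13.2 ± 4.91 TPM. TIP3-1 (GRMZM2G305446), a seed vacuole aquaporin gene, rose from 17.2 ± 4.68 to 49.7 ± 18.3 TPM. MPI (GRMZM2G028393), a proteinase inhibitor gene, rose from 409 ± 125 to 993 ± 232 TPM. Each of the 10 was higher in 4 of 4 pairs, as the naming rule requires.

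Alpha zein transcripts took a larger part of the libraries labelled ded1-ref, and the other zein classes did not follow them. Of 21 alpha zein genes tested, 20 rose (19 without the replicate block), and z1C1_8 did not pass on the TPM scale (log2 change 0.05; 0.89 in the scaled test). z1C1_12 (GRMZM2G088365) rose from 956 ± 391 to 5995 ± 822 TPM (SD, n = 4; log2 change 2.73 ± 0.16 SE, limma adjusted p = 1.3e-07). z1B_8 (GRMZM2G025763) rose from 1955 ± 660 to 6016 ± 876 TPM, z1C1_11 (GRMZM2G088273) from 50.3 ± 22.6 to 207 ± 59.8 TPM and z1C1_7 (GRMZM2G346897) from 3322 ± 498 to 5991 ± 275 TPM. Of the 5 gamma, beta and delta zein genes, gz16, gz27, bz15 and dzs18 were lower on the TPM scale, with log2 changes from -0.86 to -0.39 (gz27 only with the replicate block; limma adjusted p = 0.0607 without it). Their direction rests on the scale: in the scaled test bz15, dzs18, gz16 and gz27 stood at -0.02, -0.02, 0.09 and 0.46 with none past the threshold, and gz50 passed only there (1.06). The zein list stood higher than the other genes (camera adjusted p = 7.7e-31, 26 genes), with an adjusted p = 0.112 with an estimated correlation.

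As a share of all TPM, alpha zein genes went from 24.4% ± 1.89 to 36.0% ± 1.80 (SD, n = 4; exact two-sided permutation p = 0.0286, the smallest this test allows). The gamma, beta and delta zein genes together went from 6.15% ± 0.940 to 4.11% ± 0.597 (exact p = 0.0286). Their ratio, which no scaling of a library can alter, was 4.07 ± 0.898 in normal endosperm and 8.86 ± 0.956 in the libraries labelled ded1-ref (SD, n = 4; exact p = 0.0286). The split into classes was chosen after the values were seen. These sums, and the zein share that follows, cover only zein genes matched by name. The planned measure, the zein share of recovered reads, was 28.5% ± 1.61 and 41.1% ± 3.25 (n = 4 per group, exact p = 0.0286). Each of these measures differed in the same direction in 4 of 4 pairs, but an exact paired test over 4 pairs cannot reach 0.05.

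**Figure D2:**
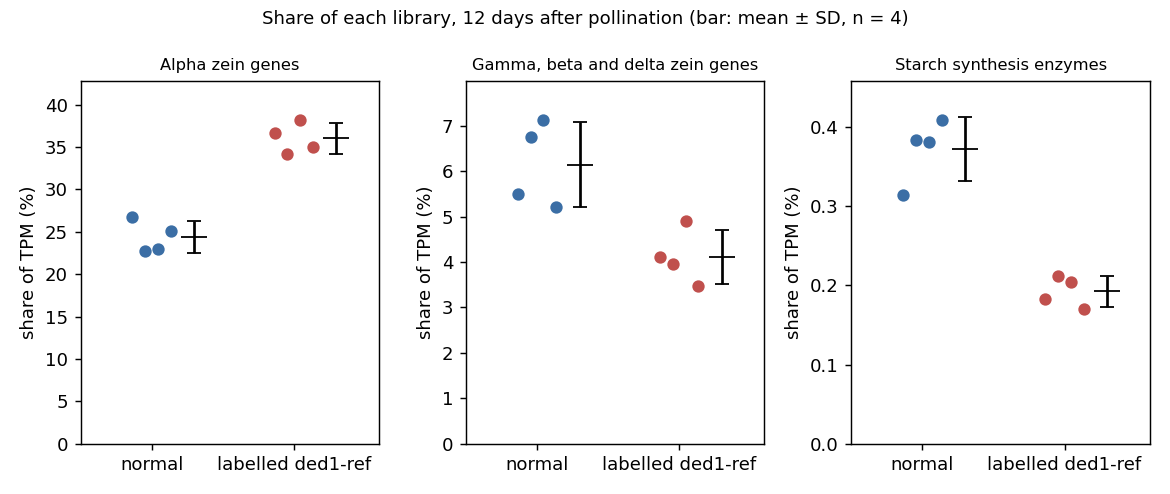
Share of all TPM, in percent (vertical axes, each from 0), taken by alpha zein genes, by gamma, beta and delta zein genes and by starch synthesis enzymes in each normal library and each library labelled ded1-ref (1 point per library; bars are mean ± SD, n = 4). The alpha zein share lies between 34.2% and 38.2% in the libraries labelled ded1-ref and between 22.7% and 26.7% in the normal ones, while the shares in the other panels are lower in the libraries labelled ded1-ref.

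Starch synthesis genes as a sum lost share of the library, and few passed relative to the median gene. Their share of recovered reads was 0.837% ± 0.0805 in normal endosperm and 0.492% ± 0.0395 in the libraries labelled ded1-ref (SD, n = 4; exact two-sided permutation p = 0.0286). Most of these reads were of ae1, with 350310 over the normal libraries and 272940 over those labelled ded1-ref, so the share mainly follows that gene. Some starch genes known to be abundant were listed at low levels and add little to it. On the TPM scale 10 of 11 tested genes were lower, and 10 when adjusted over the list alone, but in the scaled test only ss2 was lower. ss1 (GRMZM2G129451), a starch synthase gene, stood at 398 ± 68.5 and 186 ± 34.04 TPM, and ae1 (GRMZM2G032628), the amylose extender branching enzyme gene, at 2667 ± 296 and 1493 ± 125 TPM. bt1 (GRMZM2G144081), the brittle1 carrier of ADP-glucose, stood at 462 ± 84.0 and 169 ± 85.4 TPM, and SH-1 (GRMZM2G089713), the shrunken1 sucrose synthase gene, at 136 ± 44.1 and 48.3 ± 13.2 TPM. The scaled log2 changes of these 4 were -0.25, 0.01, -0.72 and -0.63, and none passed. The list did not pass the test against the other genes (camera adjusted p = 0.217), but did without replicate 1 (0.0409). The list of grain-fill transcription factors was lower on the TPM scale in 4 of 4 tested genes, also when adjusted over the list alone, and in none in the scaled test. o2 (GRMZM2G015534), opaque2, stood at 166 ± 31.5 and 105 ± 24.7 TPM and PBF (GRMZM2G146283), the prolamin-box binding factor, at 254 ± 34.5 and 160 ± 18.9 TPM. Their scaled log2 changes were 0.17 and 0.18, of the opposite sign. For MADS47 and IDDveg9 the scaled log2 changes were -0.39 and -0.68 (camera adjusted p of the list = 0.323).

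Most tested genes of the basal transfer layer, the cells through which the kernel takes up sugar from the mother plant, fell. The list fixed before the data were examined asked for 27 symbols and matched 11 genes. In it 7 of 7 tested genes were lower on the TPM scale, 7 when adjusted over the list alone, and 5 fell on both scales (3 without the replicate block). The list stood lower than the other genes (camera adjusted p = 0.0089), with an adjusted p = 0.633 with an estimated correlation. The wider list of transfer layer antifungal and response genes shares members with the fixed list, betl10 and bap2 among them. In the wider list, 13 of 13 were lower on the TPM scale and 10 fell on both (8 without the replicate block; camera adjusted p = 6.8e-05; adjusted p = 0.569 with an estimated correlation). betl-9 (GRMZM2G087413) fell from 529 ± 201 to 109 ± 34.9 TPM (SD, n = 4), betl10 (GRMZM2G091445) from 213 ± 69.9 to 53.6 ± 20.1 TPM, bap2 (GRMZM2G152655) from 48.7 ± 18.9 to 9.13 ± 3.68 TPM and MEG1 (GRMZM2G354335) from 54.4 ± 21.98 to 16.5 ± 6.27 TPM. betl3 (GRMZM2G175976) fell from 16.7 ± 5.46 to 4.71 ± 2.36 TPM. MEG1 and betl3 passed the scaled test only with the replicate block (adjusted p = 0.144 and 0.0839 without it). Their summed TPM, as a multiple of that of the median tested gene, was 44.3 ± 14.1 in normal endosperm and 21.3 ± 11.1 in the libraries labelled ded1-ref for the fixed list (SD, n = 4; exact two-sided permutation p = 0.0571), and lower in 4 of 4 pairs. In this measure ded1-ref replicate 3 stood apart, at 37.9 against 15.5 to 16.1 in the other libraries labelled ded1-ref. Of the embryo-surrounding region list, 3 genes were tested and none passed, also when adjusted over the list alone. The list passed the test against the other genes, with direction up, only without replicate 2 or replicate 3 (camera adjusted p = 0.0775 with all libraries, 0.0035 and 0.0402 without them). esr-6 stood at 16.1 ± 8.93 and 15.3 ± 4.38 TPM and ESR1 at 15.2 ± 6.87 and 14.8 ± 6.62 TPM.

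**Figure D3:**
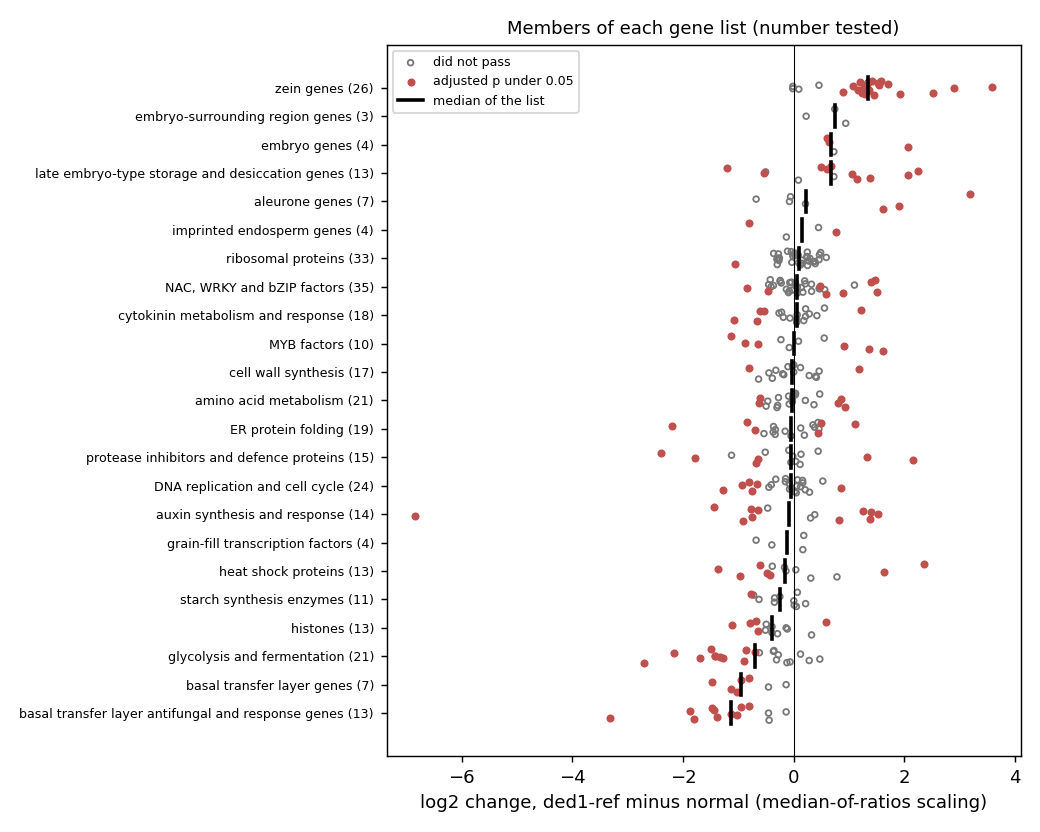
Log2 change in the scaled test (horizontal axis, ded1-ref minus normal) of each tested member of 23 gene lists (rows, with the number tested), filled red where limma's adjusted p is under 0.05 and open grey otherwise. Black bars are list medians, which run from -1.14 for the transfer layer antifungal and response genes to 1.34 for the zein genes.

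Many sugar breakdown genes fell. Of 21 tested genes of glycolysis and fermentation, 20 were lower on the TPM scale and 11 fell on both (camera adjusted p = 1.9e-04; adjusted p = 0.569 with an estimated correlation). ald1 (GRMZM2G057823), an aldolase gene, fell from 2433 ± 297 to 559.8 ± 60.4 TPM and aldolase2 (GRMZM2G066024) from 942 ± 91.3 to 195.7 ± 26.5 TPM. gpi (GRMZM2G065083), glucose-6-phosphate isomerase, fell from 388 ± 35.5 to 86.6 ± 20.03 TPM and PK (GRMZM2G003883) from 29.2 ± 4.23 to 2.02 ± 0.934 TPM. Of 13 histone genes 11 were lower on the TPM scale and 4 fell on both (camera adjusted p = 0.0116; adjusted p = 0.569 with an estimated correlation). These were 2 genes named H4C13 (GRMZM2G181153, from 149 ± 11.7 to 38.7 ± 8.88 TPM, and GRMZM2G084195, from 142 ± 4.46 to 51.0 ± 8.09 TPM), his2b5 (from 515 ± 86.4 to 166 ± 19.4 TPM) and H3C2 (from 90.0 ± 13.99 to 31.0 ± 4.44 TPM). Of 24 genes of DNA replication and the cell cycle, 5 fell on both scales (camera adjusted p = 0.329), among them RNRS1, a ribonucleotide reductase gene (from 73.7 ± 13.6 to 16.9 ± 5.03 TPM), RNRS3 (from 31.95 ± 6.997 to 9.65 ± 1.21 TPM), PCNA, the replication clamp (from 12.5 ± 1.45 to 3.93 ± 1.23 TPM), and cyclin8 (from 5.78 ± 1.78 to 1.31 ± 0.303 TPM).

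The aleurone list, for the outer cell layer of the endosperm, stood higher than the other genes, although only some of its members rose. On both scales 3 rose and 0 fell, so the lower calls below hold on the TPM scale alone. Of 7 tested, 3 were higher and 3 lower on the TPM scale, with the same numbers when adjusted over the list alone (camera adjusted p = 0.00203; adjusted p = 0.569 with an estimated correlation; 0.177 in the scaled test). The genes that rose belong to anthocyanin pigment synthesis: a2, bronze-2 (GRMZM2G016241, from 0.169 ± 0.164 to 2.51 ± 0.902 TPM) and its regulator c1 (GRMZM2G005066, from 2.52 ± 1.90 to 5.94 ± 3.02 TPM, higher in 3 of 4 pairs). IDDveg9 (GRMZM2G129261) stood at 35.8 ± 10.3 and 12.98 ± 5.42 TPM and dek1 (GRMZM2G321753), needed for aleurone identity, at 13.7 ± 1.04 and 7.88 ± 3.54 TPM, with scaled log2 changes of -0.68 and -0.06 that did not pass. The median of the list was -0.46 and its mean 0.26 on the TPM scale.

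Markers of other kernel parts were checked for tissue carried over in dissection. Of 4 tested embryo genes, MGL3 (GRMZM2G096475) rose, from 6.17 ± 3.47 to 19.1 ± 13.4 TPM, also when adjusted over the list alone (3 of 4 pairs; limma adjusted p = 0.0096, and 0.0782 without the filter on low values), and 3 were higher in the scaled test (MGL3, ole1 and wox2A; without the replicate block ole1 did not pass, adjusted p = 0.105). Of the matched embryo genes too low for a test, dhn1 had means of 0.331 TPM in normal endosperm and 2.69 TPM in the libraries labelled ded1-ref. vp1 stood at 0.418 and 0.554 TPM. CADR1, KN-1, glb2, wus1 and wox5B were at 0 TPM in normal endosperm and at most 0.0701 TPM in the libraries labelled ded1-ref. The embryo list stood higher than the other genes (camera adjusted p = 0.00467; adjusted p = 0.622 with an estimated correlation). The wider list of late embryo-type storage and desiccation genes also stood higher (camera adjusted p = 0.00119; adjusted p = 0.633 with an estimated correlation), although its median was -0.16 and its mean -0.05 on the TPM scale. Of its 13 tested genes 8 were higher and 2 lower in the scaled test, and 3 rose and 2 fell on both scales (2 and 2 without the replicate block): TIP3-1 rose, while Emb12 (GRMZM2G119691) fell from 133 ± 19.8 to 51.5 ± 11.8 TPM and dehydrin3 (GRMZM2G373522) from 3.01 ± 0.881 to 0.310 ± 0.149 TPM. ole1, an abundant oil body protein gene of embryo and aleurone, stood at 385 ± 105 and 325 ± 84.0 TPM. Of the maternal kernel tissue list 7 genes matched and none reached the level for a test; m6 was its highest member, at a mean of 2.16 TPM in normal endosperm and 0.831 TPM in the libraries labelled ded1-ref.

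Auxin genes moved apart. Of 14 tested, 4 rose and 6 fell on both scales (3 and 5 without the replicate block; camera adjusted p = 0.323, with a test direction up while the median and mean of the list were -0.73 and -1.01 on the TPM scale). Besides yuc, the response factor gene ARF23 (GRMZM2G441325) fell from 11.1 ± 1.71 to 1.86 ± 0.724 TPM, ARF10 (GRMZM2G338259) from 10.6 ± 1.06 to 3.44 ± 1.70 TPM and AUX3 (GRMZM2G004696) from 16.9 ± 3.52 to 4.91 ± 1.98 TPM. Yucca6 (GRMZM2G019515), named for the enzyme family of yuc and chosen after its values were seen, rose from 27.5 ± 5.16 to 42.9 ± 14.9 TPM (limma adjusted p = 0.0113; 0.0705 without the replicate block). Of 18 cytokinin genes 1 rose and 4 fell, 2 of them without the replicate block too (camera adjusted p = 0.539). cko2 fell from 1.79 ± 0.683 to 0.0618 ± 0.0615 TPM, crr5 (GRMZM2G032496) from 11.3 ± 1.52 to 3.87 ± 1.37 TPM and the receptor gene hk3 from 3.99 ± 1.08 to 1.26 ± 0.575 TPM (scaled adjusted p = 0.0504 without the replicate block). Of 10 genes named for MYB factors, 2 rose and 3 fell (1 and 2 without the replicate block; camera adjusted p = 0.210), and MYB129 fell from 3.60 ± 1.52 to 0.721 ± 0.285 TPM. Of 4 imprinted genes tested, MEG1 fell and NRP1 (152 ± 12.6 and 80.3 ± 25.7 TPM) was lower on the TPM scale alone, also when adjusted over the list alone (camera adjusted p = 0.872).

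The remaining lists did not pass the test against the other genes with all libraries, and with an estimated correlation no list at all passed. Of 35 NAC, WRKY and bZIP genes 3 rose and 2 fell on both scales, 2 and 1 without the replicate block, and 6 were higher and 2 lower in the scaled test (camera adjusted p = 0.329), with lip15 at 552 ± 208 and 275 ± 142 TPM and a scaled log2 change of -0.24 that did not pass. Of 13 heat shock genes 2 rose and 5 fell, and 2 and 2 without the replicate block (camera adjusted p = 0.539): HSP18 (GRMZM2G404249) fell from 33.0 ± 7.09 to 6.74 ± 1.64 TPM while hsp82 rose. Of 19 genes of protein folding in the endoplasmic reticulum 3 fell and none rose, while 3 were higher and 3 lower in the scaled test (camera adjusted p = 0.343), with pdi2 (GRMZM2G163421), a protein disulfide isomerase gene, falling from 27.1 ± 1.18 to 2.79 ± 0.780 TPM. Of 15 protease inhibitor and defence genes 2 rose and 4 fell, and 1 and 4 without the replicate block (camera adjusted p = 0.989), with the cystatin gene cc6 (GRMZM2G401328) falling from 9.85 ± 4.21 to 0.422 ± 0.353 TPM while MPI rose. Of 21 amino acid metabolism genes 3 were higher and 2 lower in the scaled test, and 2 fell on both scales (camera adjusted p = 0.637), alt (GRMZM2G088064) from 904 ± 107 to 328 ± 56.3 TPM and psat1 from 204 ± 33.3 to 78.6 ± 29.9 TPM. Of 17 cell wall genes, Bk2L6 fell, from 17.3 ± 8.15 to 5.24 ± 2.502 TPM (camera adjusted p = 0.872). Without the replicate block alt, psat1 and Bk2L6 did not pass the scaled test (adjusted p = 0.0825, 0.0672 and 0.105). Of 33 ribosomal protein genes 27 were lower on the TPM scale and only L29 fell on both, from 28.5 ± 5.56 to 7.34 ± 2.35 TPM (camera adjusted p = 0.0775; 0.0313 without replicate 3 and 0.0091 without replicate 4, with direction down). The set test compares a list with the other genes, so that the MYB, NAC with WRKY and bZIP, cytokinin and embryo-surrounding region lists had an upward direction with medians of -0.50, -0.54, -0.58 and -0.04 on the TPM scale.

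The authors' deposited table calls 3761 transcript rows at an adjusted p under 0.05, 2035 of them higher and 1726 lower in ded1-ref. For each gene the authors' row with the highest mean signal was compared with the sum over all its rows here. A gene that the authors call only on another row thus counts as not called. By this rule 2822 of the genes tested here are called in the authors' deposited table. On the TPM scale 1755 of these were also called, and 1705 of the 1755 (97.2%) had the direction of the authors' deposited table. In the scaled test 2587 were called in both, and 2587 had the same direction. For yuc the authors' deposited table gives a log2 fold of -7.69 and for fl3 -3.28. Both sets of calls come from the same libraries, so their overlap is no independent evidence.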

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

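In 212 groups of 4 libraries tested, 10 had a library far from the other 3, and chance gives such a library in about 1 of 20 groups, so the number of them is no more than chance allows. Of the 10, 4 are ded1-ref replicate 3 standing high: ded1 at 101 TPM against 67.3 to 69.7 TPM in the others, betl-9 at 161 TPM against 91.3 to 91.8 TPM, bap2 at 14.6 TPM against 6.85 to 8.01 TPM, and the summed transfer layer TPM over the median gene's at 37.9 against 15.5 to 16.1. Normal replicate 3 stood high in cyclin8, at 8.45 TPM against 4.79 to 5.08 TPM, and in MGL3, at 11.3 TPM against 3.98 to 5.10 TPM. Normal replicate 4 stood low in PDIL5-1 (GRMZM2G073628), at 15.2 TPM against 17.4 to 17.8 TPM, and high in H4C13 (GRMZM2G181153), at 166 TPM against 141 to 145 TPM. ded1-ref replicate 4 stood low in IDDveg9, at 4.95 TPM against 14.6 to 16.4 TPM. The level of ded1 over that of the median gene was 5.69 in normal replicate 1 against 4.69 to 4.75 in the other normal libraries.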

How the results depend on the processing

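The scale decides the number and the balance of calls. Against 482 genes higher and 9539 lower on the TPM scale, there were 1687 and 1444 with median-of-ratios scaling, 1439 and 1762 with upper quartile scaling, and 1814 and 1472 with limma-voom on recovered reads with size factors and the replicate block. Of these 3 alternatives, the first and the last bring the middle of the distribution close to 0 by construction. Upper quartile scaling sets the upper quartiles equal and left the median change at -0.0638. At a change of at least 2-fold, against 177 and 3004, there were 626 and 518, 560 and 589, and 916 and 825 under the same 3, and 270 and 4904 with a pseudocount of 0.1. A smaller pseudocount enlarges the folds of low genes by construction. The filters and the removal of the block kept the counts of higher and lower genes within 1.5 times, as did leaving out a replicate on the TPM scale (359 to 539 higher, 7963 to 9240 lower). Of 93 named genes, 66 to 93 kept their direction and their side of the threshold under each alternative to the TPM test. Without the replicate block 402 genes were higher and 8842 lower. This ended the call of Myb30 and RAB15 on the TPM scale and, in a fit chosen after seeing the data, those of MYB-IF35, bZIP46, alt, psat1, MEG1, betl3, Bk2L6, hk3, hsp1 and hsp18f in the scaled test, and of genes named after their values were seen, those of Yucca6 and gz27 (TPM scale) and of ole1 (scaled test). The block changed no other call of a gene given by name in the text and no call of a list test, but counts of genes within lists moved, as from 20 to 19 zein genes that rose, from 3 to 2 late embryo-type genes that rose and from 6 to 5 auxin genes that fell. Without it 401 genes rose and 1242 fell on both scales. Without a filter Myb30 and MGL3 did not pass. Under median-of-ratios, upper quartile and limma-voom scaling, the log2 changes of opposite sign were 0.74, 0.67 and 0.81 for ESR1, 0.18, 0.11 and 0.17 for PBF, and 0.17, 0.089 and 0.16 for o2, and under the first alone 0.0092 for ae1; the shift of the median shows the cause. With a replicate left out, ESR1 ran from -0.48 to 0.32 and esr-6 from -0.31 to 0.50, and the cause was not tested. With median-of-ratios scaling the lists of auxin (adjusted p = 0.959), cytokinin (0.938), imprinted (0.873) and ribosomal protein genes (0.781) changed direction, and with a replicate left out so did those of cell wall genes (0.758 to 0.957) and of protease inhibitor and defence genes (0.523 to 0.908); none passed, and the cause was not tested. Leaving out a replicate brought past the threshold the starch list (0.0409 without replicate 1), the embryo-surrounding region list (0.0035 and 0.0402 without replicates 2 and 3) and the ribosomal protein list (0.0313 and 0.0091 without replicates 3 and 4). An estimated correlation ended the call of 8 lists, and scaling that of the aleurone list. The zein share rose by 12.6 points and the starch enzyme share changed by -0.345 points in the exact paired test with the replicate block too, without passing, since 4 pairs are too few. With a replicate left out they ran from 11.2 to 13.3 and from -0.374 to -0.302, with an exact permutation p = 0.1, the smallest for 3 against 3 libraries. Against 97.2% of shared calls with the direction of the authors' table, 100% had it at an adjusted p under 0.01; the cause was not tested. The alternatives from here to the scaled test without the block were chosen after seeing the data. With median-of-ratios scaling or limma-voom on recovered reads, that percentage was 100% and 100%. With limma-voom on library totals 313 genes were higher by at least 2-fold and ESR1 stood at 0.12. With zein genes left out of TPM the values were 311 and 0.17, and the zein genes have no value there; the cause was not tested. Testing transcript rows gave 484 higher and 9726 lower. In the scaled test itself, leaving out a replicate gave 1147 to 1446 higher and 917 to 1209 lower genes, with fewer libraries in each fit, and log2 changes from -0.26 to 0.26 for dek1, -0.044 to 0.014 for AHAS108, -0.0023 to 0.39 for o2, -0.45 to 0.16 for NRP1 and -0.089 to 0.13 for ae1; these lie around 0 and the cause was not tested. It had 1397 higher and 1242 lower genes without the block. Under these alternatives to the scaled test 75 to 83 of the 93 named genes kept their direction and their side of the threshold. Leaving out replicate 2 ended the most calls, 16. The DESeq2 Wald test and the edgeR fits of the plan were not run. Depth limits what can be said of genes too low for the filter, such as A1 and c2. Rows with 1 read stood at a median of 0.0823 TPM in the shallowest library.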

Other observations

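Several genes with no informative name changed as much as the named ones (all genes in this paragraph and the next, other than f3h and a2, were chosen after their values were seen). GRMZM2G154216 went from 168 ± 19.0 to 1.16 ± 0.0823 TPM (SD, n = 4), a log2 change of -6.28 on the TPM scale and -5.62 in the scaled test, and GRMZM2G334631 from 448 ± 89.9 to 2.63 ± 2.82 TPM. AC233893.1_FG001 rose from 17.7 ± 7.38 to 247 ± 141 TPM. GRMZM2G012928 rose from 1838 ± 727 to 14534 ± 1920 TPM, a log2 change of 3.04 and 3.89 in the scaled test, which puts it among the 20 most abundant genes. What these genes encode is not given in the sources used here.

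A1 and c2, anthocyanin genes too low for a test, showed reads in the libraries labelled ded1-ref alone. A1 had 0 recovered reads in each of the 4 normal libraries and 19, 17, 1 and 13 in ded1-ref replicates 1 to 4, and c2 had 0 in each normal library and 61, 13, 0 and 4. f3h stood at 32.1, 11.2, 4.26 and 15.8 TPM in ded1-ref replicates 1 to 4 and a2 at 15.6, 7.84, 1.73 and 7.22 TPM, so that replicate 3 was the lowest for each of these 4 genes. bronze (GRMZM2G165390), also too low for a test, had 1, 0, 0 and 0 recovered reads in normal replicates 1 to 4 and 12, 4, 0 and 0 in ded1-ref replicates 1 to 4. NAC78, from the grain-fill list, was too low in too many libraries for a test, with means of 2.91 TPM in normal endosperm and 0.0281 TPM in the libraries labelled ded1-ref.

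The groups differ beyond what regrouping the libraries gives. Without the block, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many genes: it called 9244 and the highest of the others called 1. That is a share under 0.05 and the smallest these splits allow, but they ignore the stated pairing. With the block, 8 splits part all 4 pairs, too few for a share under 0.05; the real one called 10021 genes and the highest of the others 0, with 1 split, the real one, as high.

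In the 2 paragraphs that follow, both tests of the transfer layer genes were chosen only after their result was seen, and the other tests were set before.

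Most genes were lower on the TPM scale in the libraries labelled ded1-ref, by a median log2 change of -0.68. With every library thinned to the reads of the smallest, the median was -0.682. TPM keeps no depth and random thinning keeps the expected shares, so this outcome was nearly fixed beforehand and is no test of depth. The named zein genes alone do not account for the shift, since without them, and with TPM brought back to their full sum, the median stayed at -0.545 with an SD of 0.153 between pairs. Several of the 20 most abundant genes have no informative name and stayed in, so zein genes without a matched name are not covered. Without the 20 most abundant genes the median was -0.224 with an SD of 0.137, too near the bound of -0.2 set beforehand to decide. A few genes taking most of the reads may thus be most of the cause, and whether the rest is biological stays open. Those 20 genes took 49.6% ± 2.57 of TPM in normal endosperm and 66.7% ± 2.55 in the libraries labelled ded1-ref (SD, n = 4; exact permutation p = 0.0286).

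Transfer layer genes were lower than the median gene in the libraries labelled ded1-ref. A smaller share of that tissue in the pools would lower all members by a common factor. The limma-voom changes of the 7 genes of the fixed list were unequal (Cochran Q over degrees of freedom 6.15), but this rests on EBE-1: without it the value was 1.88. Q also takes the genes as independent, so a smaller share of the tissue stays open. In the scaled test, where the median gene does not move, the median log2 change of the 7 genes was -0.947, with an SD of 0.512 between pairs. Relative to the median gene it was -0.945 on the TPM scale. Scaling divides all genes of a library by the same factor, so it hardly moves a gene relative to the median gene. This outcome was thus nearly fixed beforehand and is no test of scaling as a cause. For the list, camera gave an adjusted p = 0.633 on the TPM scale with an estimated correlation, and 0.0013 in the scaled test. Of the 7 genes 5 passed, and 3 without the replicate block. The ratio of their summed TPM to that of the median gene was lower in 4 of 4 pairs, although ded1-ref replicate 3 lay above normal replicate 4 of another pair (37.9 against 26.7). An effect of the mutation on these genes remains among the open explanations, untested here beyond the comparison itself.

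Some starch genes known to be abundant in endosperm were listed at low levels, among them sh2, bt2 and GBSS1, and transcript rows that share reads may be the reason. If reads shared between the transcripts of a gene were left uncounted, genes with more rows would stand lower. The median TPM in normal endosperm of 2459 genes with 4 or more rows was 0.573 of that of 17030 genes with 1 row, between the bounds set beforehand for and against, so the test did not decide. Of the 3 genes, GBSS1 has 6 rows, while sh2 and bt2 have 3 rows each and belong to neither class compared. The upper quartile was 0.224 of that of genes with 1 row, a value not named beforehand. Levels of genes with many rows, and sums over them, are uncertain for this reason.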
